A study of Mus musculus with 6 samples.

How the data were processed

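RNA-seq of 6 libraries of differentiated C2C12 cells was compared, 3 labelled WT and 3 labelled FHL3 KO, all from day 4. Per the labels' protocols, total RNA was isolated with Trizol and freed of genomic DNA, and libraries of amplified RNA followed the Illumina protocol. Per the submitters' processing notes, Trim Galore 0.6.6, HISAT2 2.2.1, featureCounts 2.0.1 and DESeq2 1.28.1 were used with the mouse build mm10, with no role or order given. The annotation, the strand setting, the treatment of reads shared between genes and the step that made the table are not given in the sources used here.

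The deposited table gives a decimal value per gene and library, read here as FPKM (fragments or reads per kilobase and per size of the library). Per the file headers only gene IDs, names and samples are known, so the unit was inferred from the values. Each column sums to a different total, from 424987 to 494176, and none to the fixed total of TPM. Genes shorter than 150 bases shared a smallest common value within a library, such as 0.187 in WT replicate 3, and its multiples. Low values of genes of at least 300 bases lay within 0.05 of a multiple of it in 9.5% to 9.7% of cases, against 10% by chance, so the values are divided by a length and are not CPM. If that step is 1 fragment, the relative depths were 0.928, 0.907 and 0.864 for WT replicates 1 to 3 and 0.859, 0.983 and 1 for the replicates labelled FHL3 KO. Absolute depth is unknown, and no counting interval is given. An exact 0 can be a failed estimate: 24 tested genes were at 0 in a library and at 5 FPKM or more in another of the same group.

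The table has 55420 rows. Of these, 7 rows that shared 3 repeated gene IDs were left out, and 1492 rows carry no gene name. Gene IDs were matched to GENCODE M21 (GRCm38, the build that mm10 names), which holds 94% of all IDs and 99.7% of those tested, for coordinates, exon length and GC content. Where a symbol had several records, list members used the record with the highest mean.

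Because the values are not counts, the count tests planned for a count table were replaced by the planned test for normalized values. Genes with a mean of at least 1 FPKM in at least 1 group were kept (12528 genes). Log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 (moderated test with a mean-variance trend, two-sided), without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, while levels are mean FPKM ± SD. Gene lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 21 lists with at least 5 measured members, and again with an estimated correlation and with fry. The myosin heavy chain shares were compared by exact permutation.

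The comparison, the 25 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took Fhl3 and Yy1; the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, with a mean of at least 5 FPKM in a group and no predicted-gene symbol; the 4 members of each list with the smallest p; and 6 myosin heavy chains, Myod1 and Myog. It gave 110 genes, of which the text gives a part. Other list members (Acta1, Trdn, Cdkn1a, Mybpc2, Tnnt3, Tnni2, Atp2a2, Hspa5, Slc7a11, Ddit3, Ddit4, Dnajb9 and Sdf2l1), Alb and genes in the closing section were chosen after their values were seen. Alternatives were a pseudocount of 0.1, no filter, quantile normalization, the replicate number as a block, leaving out each library, a threshold of 0.01 and the other set tests. Chosen after seeing the data were scaling to the same sum, median-of-ratios scaling, removal of each library's trend with exon length, or with length and GC content (splines with 5 degrees of freedom), a filter at 5 FPKM, leaving out genes listed at 0 in any library, leaving out chromosome 8, and myosin shares weighted by length.

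The steps were tested on simulated data for the 12528 genes of this comparison, with 200 genes changed. Limma recovered 29.9% of genes changed 1.5-fold, 70.1% of those changed 2-fold and 98.5% of those changed 4-fold, with 4 false calls among 136. In the data 5112 genes were called, far more than the 200 changed here, so a call needed a smaller p in the simulation. These shares therefore do not give the recovery in the data. With a length trend added to unchanged genes 193 were called, and 4 after length correction. That trend was the same in all libraries labelled FHL3 KO and of a form that the correction fits. In the data the trend differed between libraries, so this does not show how well the correction works there. The main counts are not corrected for length. None of 50 random lists was called, but the simulated genes were drawn independently, so this does not test lists of correlated genes. In simulated chromosomes and gene orders without a shift, 2 of 50 and 6 of 100 runs passed 0.05. These runs were shuffles of the observed changes judged against other shuffles, so a share near 0.05 was set in advance. They do not test neighbouring genes that change together. Liver, lung, kidney, heart, brain, pancreas and blood marker lists were written after the transcripts peculiar to WT replicate 1 had been seen and, apart from Myh6 and Hba-a1, without genes already looked at. Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.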

Results

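RNA was measured in C2C12 cells, a mouse myoblast line that fuses into myotubes when serum is lowered. Cells were collected on day 4 of differentiation in medium with 2% horse serum, after growth in 10% fetal bovine serum. The labels give 2 genotypes with 3 libraries each, WT and a knockout of FHL3, a LIM-domain protein of striated muscle. The series title ties FHL3 to fast glycolytic fibres, to the transcription factor YY1 and to glycolytic metabolism, so the comparison asks how the muscle gene programme differs between the genotypes. The deposited table holds FPKM values without read counts. The FPKM summed to between 424987 and 494176 per library, and, if the smallest common value of short genes stands for 1 fragment, which was not tested, the relative depths of the 6 libraries lay between 0.859 and 1. Log2 values correlated across genes at 0.977 to 0.991 within a group and at 0.93 to 0.959 between groups, and the leading principal component, with 69% of the variance, separated the genotypes as labelled. WT replicate 1 stood apart in 63 genes that exceeded 1 FPKM and 10 times the value of every other library, among them the liver transcript Alb at 56.0 FPKM. The other libraries had between 0 and 6 such genes. The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The sample titles name no clone for the libraries labelled FHL3 KO, so clone and genotype cannot be told apart.

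Fhl3 RNA was higher, not lower, in the libraries labelled FHL3 KO. Fhl3 (ENSMUSG00000032643, chromosome 4, 124700701 to 124708611, GRCm38) stood at 27.8, 30.03 and 33.7 FPKM in WT and at 57.2, 53.5 and 58.9 FPKM in the libraries labelled FHL3 KO. The means were 30.5 ± 3.0 and 56.5 ± 2.8 FPKM (SD, n = 3 each), and the limma adjusted p of the log2 change of 0.87 (SE 0.092) was 0.000547. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. The RNA level of the targeted gene thus does not bear out the label. By itself it does not contradict the label either, since a knockout allele can leave or raise the transcript. The groups are therefore named by their labels throughout, and "rose" and "fell" describe the libraries labelled FHL3 KO relative to WT. The table has a single value per gene and does not show which exons the reads covered. Yy1 was at 14.3 ± 1.1 FPKM in WT and 14.8 ± 1.4 FPKM in the libraries labelled FHL3 KO (limma adjusted p = 0.74, exact p = 0.7). Of the related genes, Fhl2 fell from 59.4 ± 1.7 to 41.5 ± 3.9 FPKM (limma adjusted p = 0.00394), while Fhl1 was at 416.9 and 389.1 FPKM (adjusted p = 0.42).

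The groups differed in many genes, with myosin heavy chains among the largest changes in both directions. Slow myosin Myh7 rose from 4.21 ± 0.33 to 76.9 ± 12 FPKM, and its chromosome 14 neighbour Myh6, the alpha cardiac myosin, from 1.24 ± 0.98 to 16.8 ± 3.4 FPKM. Fast myosin Myh4 fell from 46.4 ± 7.0 to 2.13 ± 0.18 FPKM. The matrix protease Mmp2 fell from 31.0 ± 1.3 to 0.085 ± 0.037 FPKM, against the direction of most other chromosome 8 genes, and the glutathione peroxidase Gpx3 from 85.6 ± 9.9 to 4.55 ± 0.62 FPKM. Of 12528 genes tested with limma, 5112 passed an adjusted p of 0.05, of which 2462 (48.2%) rose and 2650 fell. With the FPKM of each library scaled to the same sum, the median of all genes moved to -0.12 on the log2 scale and 35.5% of 4873 calls were rises. The change reached at least 2-fold for 761 genes on the log2(FPKM + 1) scale, which understates the change of low genes. Leaving out WT replicate 2 lowered the calls to 3272. The groups did not overlap for 53.8% of the tested genes, against 10% by chance for 3 against 3.

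The largest rises besides the myosins were in Pnmal2 (0.13 ± 0.050 to 11.3 ± 1.7 FPKM), Stmn2, a microtubule regulator of neurons (8.33 ± 0.55 to 86.3 ± 2.3 FPKM), Cap2, an actin regulator of striated muscle (1.60 ± 0.11 to 21.8 ± 2.9 FPKM), Igfbp3, which binds insulin-like growth factors (0.41 ± 0.13 to 9.92 ± 2.2 FPKM), and Reep1 (0.32 ± 0.079 to 8.74 ± 0.38 FPKM). Lbx1, a homeobox factor of migrating muscle precursors, rose from 0.32 ± 0.069 to 8.10 ± 0.58 FPKM, the keratin Krt19 from 0.88 ± 0.22 to 11.8 ± 2.3 FPKM and the ubiquitin hydrolase Uchl1 from 2.13 ± 0.22 to 19.3 ± 2.6 FPKM. The largest falls included the secreted Ccn3 (144.6 ± 11 to 12.4 ± 0.58 FPKM) and Xirp2, an actin-binding protein of muscle (10.8 ± 1.5 to 0.14 ± 0.029 FPKM). Gsta2, a glutathione transferase, was at 9.40, 10.0 and 9.25 FPKM in WT and was listed at 0 in 2 libraries labelled FHL3 KO and at 0.11 FPKM in the other. The calcium buffer of fast fibres Pvalb was at 11.8, 11.3 and 12.7 FPKM in WT and was listed at 0.48, 0 and 0.52 FPKM. Each of these 12 genes had a limma adjusted p of 5.2e-05 or lower. A record of the cytoskeletal gene Septin2 (ENSMUSG00000116048) also ranked here, at 57.2, 9.34 and 34.3 FPKM in WT and at 0, 0 and 8.16 FPKM, but it overlaps the main Septin2 record at 70.3 and 72.9 FPKM and is uncertain. Its call (limma adjusted p = 0.0177) ended without a filter (0.084), without WT replicate 1 (0.0594) and without the replicate 1 labelled FHL3 KO (0.0645).

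Among the myosin heavy chains, embryonic Myh3 and slow Myh7 gained and the adult fast isoforms lost. Of the summed FPKM of 6 isoforms, Myh3 took 45.8% ± 1.2 in WT and 81.5% ± 0.61 in the libraries labelled FHL3 KO (SD, n = 3), and Myh7 took 1.502% ± 0.21 and 11.5% ± 0.77. The share of Myh1 was 33.4% ± 0.61 against 5.76% ± 0.22, that of Myh4 16.4% ± 0.52 against 0.32% ± 0.018, that of Myh2 1.55% ± 0.10 against 0.24% ± 0.018, and that of neonatal Myh8 1.36% ± 0.18 against 0.71% ± 0.019. The groups were apart for every isoform, with an exact two-sided permutation p of 0.1 for each, before and after adjustment over the 6 isoforms, which is the smallest 3 against 3 allows. In level, Myh3 rose from 130 ± 19 to 544.1 ± 50 FPKM, Myh1 fell from 94.5 ± 11 to 38.4 ± 2.2 FPKM and Myh2 from 4.37 ± 0.28 to 1.57 ± 0.17 FPKM. Myh8 was at 3.85 and 4.78 FPKM and did not pass limma (adjusted p = 0.174, from 0.011 to 0.441 over the alternatives). Myh1, Myh2, Myh4 and Myh8 are similar in sequence and lie side by side on chromosome 11, as Myh6 and Myh7 do on chromosome 14. How reads shared between such copies were counted is not given in the sources used here, so their division is uncertain.

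**Figure D1:**
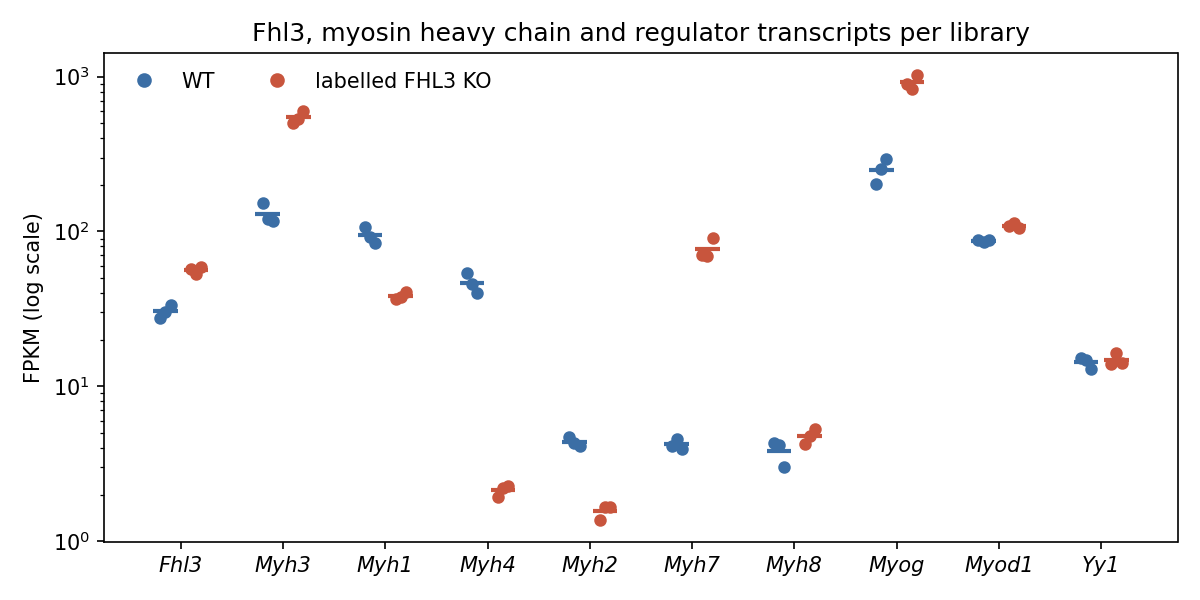
FPKM of Fhl3, 6 myosin heavy chain genes, Myog, Myod1 and Yy1 on a log axis, with a point per library (3 WT, 3 labelled FHL3 KO) and a line at each group mean. Fhl3, Myh3, Myh7 and Myog lie higher in the libraries labelled FHL3 KO, and Myh1, Myh2 and Myh4 lie lower.

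The fast fibre genes split. Of 15 measured members, 7 rose and 5 fell, the same counts as those adjusted over the list alone. The 5 that fell were Myh4, Myh1, Myh2, Pvalb and the myosin-binding protein Mybpc2. Those that rose included the calcium pump Atp2a1, from 79.4 ± 5.5 to 158.6 ± 11 FPKM (limma adjusted p = 0.000281), and the fast troponins Tnnt3 and Tnni2, at log2 changes of 0.84 and 0.86. Over the alternatives 4 to 7 members rose and 4 to 5 fell. The mean log2 change of the list was -0.31, its median 0.17, and camera ranked it upward without a call (adjusted p = 0.826). The signs thus differ, as fry, which asks whether the members move one way on balance, called the list downward (adjusted p = 0.0244).

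The slow fibre genes rose. Of 12 measured members 8 rose and 0 fell (8 and 1 adjusted over the list alone, 5 to 8 and 0 to 1 over the alternatives), with a mean log2 change of 0.85. Besides Myh7 these included the calcineurin-binding Z-disc gene Myoz2, from 37.1 ± 5.3 to 112.1 ± 5.2 FPKM, the slow troponin Tnni1, from 1039 ± 56 to 2310 ± 58 FPKM, and the calcium store protein Casq2, from 374.6 ± 7.5 to 628.3 ± 8.5 FPKM. Their limma adjusted p values were 0.000115, 0.000302 and 0.000571. The calcium pump Atp2a2 was lower, at 192.3 ± 8.5 and 150.5 ± 26 FPKM, and did not pass limma (adjusted p = 0.0516). Camera called the list upward at an adjusted p of 0.0013. With an estimated correlation between genes the adjusted p was 0.335.

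Genes of sarcomere assembly and terminal differentiation rose as a group. Of 32 measured members 18 rose and 1 fell (19 and 1 adjusted over the list alone), with a mean log2 change of 0.65. Cardiac actin Actc1 rose from 212.3 ± 13 to 1069 ± 40 FPKM, the Z-disc gene Actn2 from 11.3 ± 0.16 to 54.9 ± 3.5 FPKM and the muscle methyltransferase Smyd1 from 31.3 ± 2.3 to 69.0 ± 3.9 FPKM, at limma adjusted p values of 7.91e-06, 6.93e-06 and 0.000167. Skeletal actin Acta1, on chromosome 8, rose from 1927 ± 84 to 5461 ± 240 FPKM. It shares near-identical sequence with Actc1, so the division between them is uncertain. The member that fell was Trdn, which anchors the calcium release complex (log2 change -0.95), and its call ended after length and GC correction (-0.35, adjusted p = 0.121). Camera called the list upward at an adjusted p of 6.27e-08. The adjusted p with an estimated correlation was 0.198, or 0.0439 after the trend with transcript length was removed.

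The myogenic regulators moved apart. Myog, which drives terminal differentiation, rose from 250.1 ± 47 to 916.8 ± 96 FPKM and Myod1 from 87.3 ± 1.3 to 109 ± 3.8 FPKM, while Myf5, a factor of undifferentiated myoblasts, fell from 29.5 ± 5.7 to 8.64 ± 0.84 FPKM. Their limma adjusted p values were 0.000193, 0.0101 and 0.000239. The Myod1 call, at a log2 change of 0.32, ended after length and GC correction (0.09, adjusted p = 0.476), after quantile normalization (0.16, 0.158), after scaling to the same sum (0.21, 0.0818) and without WT replicate 2 (0.31, 0.0544), and its lowest adjusted p over the alternatives was 0.00921. Of 9 measured members 4 rose and 2 fell (4 and 4 adjusted over the list alone, 2 to 4 and 1 to 4 over the alternatives), and camera made no call (adjusted p = 0.739). Of 12 myoblast fusion genes 5 rose and 2 fell, also when adjusted over the list alone, with a mean log2 change of 0.10, a median of -0.04 and an upward camera adjusted p of 0.564. Among them the fusogens Mymx and Mymk rose from 174.1 ± 12 to 341.1 ± 20 FPKM and from 363.7 ± 39 to 599.1 ± 15 FPKM, and the caveolin Cav3 from 32.4 ± 4.1 to 97.3 ± 3.6 FPKM, while the cell-surface receptor Cdon fell from 51.1 ± 6.5 to 30.2 ± 3.6 FPKM.

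Glycolysis genes, the theme of the series title, leaned upward without a call. Of 18 members 6 rose and 1 fell, also when adjusted over the list alone (3 to 7 and 0 to 3 over the alternatives). The muscle enolase Eno3 rose from 426.1 ± 52 to 869.6 ± 87 FPKM, the muscle phosphofructokinase Pfkm from 82.3 ± 7.6 to 122.7 ± 9.3 FPKM, Gpi1 from 140 ± 10 to 194.2 ± 11 FPKM and lactate dehydrogenase Ldha from 485 ± 70 to 729.3 ± 79 FPKM (limma adjusted p of 0.00106, 0.00374, 0.00536 and 0.0127). The Ldha call ended without a filter on low values (adjusted p = 0.0555, from 0.0118 over the alternatives). The mean log2 change was 0.23 and the camera adjusted p 0.0927, which fell to 0.0345 without WT replicate 3, to 0.0413 without the replicate 2 labelled FHL3 KO and to 0.0185 without a filter on low values, and ran up to 0.774 over all alternatives. Of 11 glycogen genes 2 rose and 3 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.583). The phosphorylase Pygm and the synthase Gys1 rose, from 26.2 ± 0.95 to 45.5 ± 3.7 FPKM and from 33.6 ± 0.55 to 57.5 ± 6.7 FPKM, and Ugp2 and Gbe1 fell, at log2 changes of -0.60 and -0.46. The Gbe1 change was -0.12 after length and GC correction and was no longer called (limma adjusted p = 0.348, from 0.00564 over the alternatives).

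Nuclear genes of oxidative phosphorylation rose. Of 41 measured members 20 rose and 0 fell (21 and 0 adjusted over the list alone, 12 to 22 and 0 to 1 over the alternatives), with a mean log2 change of 0.23. The mean was 0.12 without WT replicate 1, 0.14 without the replicate 3 labelled FHL3 KO and 0.35 without the replicate 2 so labelled. Examples were Uqcrfs1 of complex III, from 84.1 ± 1.7 to 130.4 ± 7.8 FPKM, the ATP synthase subunit Atp5o, from 198.7 ± 16 to 302.5 ± 14 FPKM, and Cox5a of complex IV, from 124.2 ± 12 to 199.2 ± 17 FPKM. Camera called the list at an adjusted p of 0.00077. The call ended with an estimated correlation (adjusted p = 0.715), after quantile normalization (adjusted p = 0.0981, mean 0.08) and with fry (adjusted p = 0.0691), and the adjusted p over the other alternatives ran from 6.98e-07 to 0.00746. Transcripts of the mitochondrial genome moved the other way and made up 8.56% to 8.82% of the FPKM sum in WT and 3.98% to 6.18% in the libraries labelled FHL3 KO. The mean log2 change of its 13 protein-coding genes was -0.88, and -0.43 after length and GC correction. Of 18 tricarboxylic acid cycle genes 7 rose and 1 fell, also when adjusted over the list alone (4 to 7 and 0 to 3 over the alternatives, camera adjusted p = 0.0801), Pdhb among the former at 70.5 ± 5.4 and 105.6 ± 2.5 FPKM. Of 18 fatty acid oxidation genes 6 rose and 2 fell (6 and 3 adjusted over the list alone, 2 to 6 and 1 to 3 over the alternatives, 3 and 1 without WT replicate 1, camera adjusted p = 0.314), led by Acaa2 at 31.4 ± 1.3 and 56.3 ± 1.2 FPKM. Of 8 regulators of the oxidative programme 1 rose, Ppard, and 1 fell, Gabpa (log2 changes of 0.38 and -0.81), also when adjusted over the list alone. The Ppard call ended with scaling to the same sum (0.29, adjusted p = 0.0573, from 0.00342 over the alternatives). That list had a mean of -0.004, a median of 0.14 and an upward camera adjusted p of 0.826.

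Targets of TGF-beta and BMP signalling rose, led by the inhibitors of differentiation. Of 10 measured members 8 rose and 0 fell, also when adjusted over the list alone. Over the alternatives 5 to 9 rose and 0 fell, with 5 rises without WT replicate 2. The mean log2 change was 0.66 and the camera adjusted p 0.00077. The adjusted p was 0.335 with an estimated correlation. Id2 rose from 5.20 ± 0.69 to 21.8 ± 2.6 FPKM, Id3 from 3.83 ± 0.83 to 9.22 ± 0.33 FPKM, Id1 from 7.82 ± 1.7 to 16.0 ± 2.1 FPKM and the feedback inhibitor Pmepa1 from 68.3 ± 3.7 to 124.5 ± 7.1 FPKM. Fibroblast and matrix genes moved both ways, with 3 rising and 7 falling of 15 (5 and 7 adjusted over the list alone, 2 to 6 and 4 to 7 over the alternatives, camera adjusted p = 0.338). After length correction 6 rose and 5 fell, and after length and GC correction 5 and 6. Decorin (Dcn) fell from 151.9 ± 10 to 12.1 ± 1.1 FPKM, periostin (Postn) from 108.2 ± 16 to 10.1 ± 1.3 FPKM and Col3a1 from 201.6 ± 7.2 to 122.8 ± 9.9 FPKM, whereas Col6a1 rose from 1.16 ± 0.21 to 8.18 ± 2.7 FPKM. Of 11 smooth muscle and myofibroblast genes 6 rose and 2 fell, also when adjusted over the list alone (3 to 6 and 1 to 3 over the alternatives, camera adjusted p = 0.214), and the fall of smooth muscle actin Actg2 from 36.0 ± 3.1 to 9.21 ± 0.59 FPKM had the smallest p (limma adjusted p = 3.1e-05).

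The list of the integrated stress and unfolded protein responses was called upward, with members moving both ways. Of its 18 measured members 11 rose and 3 fell (11 and 5 adjusted over the list alone), with a mean log2 change of 0.41 and a camera adjusted p of 0.0139. The adjusted p was 0.335 with an estimated correlation, 0.0858 after length correction, 0.1 after length and GC correction, 0.0702 after quantile normalization and 0.0605 with a filter at 5 FPKM, and ran down to 0.000216 over the others. Chac1 rose from 6.53 ± 1.6 to 26.6 ± 0.93 FPKM, Trib3 from 2.30 ± 0.46 to 10.8 ± 0.88 FPKM and Atf3 from 7.21 ± 0.53 to 22.1 ± 1.6 FPKM. The chaperone Hsp90b1 fell from 294.1 ± 37 to 104.4 ± 7.6 FPKM. The other members that fell were the chaperone Hspa5 and the cystine transporter Slc7a11 (log2 changes of -0.32 and -1.08, adjusted p = 0.0233 and 0.0456). The Hspa5 call ended without WT replicate 1 (0.0515) or 2 (0.0669) and without the replicate 1 (0.0732) or 3 (0.0678) labelled FHL3 KO. The Slc7a11 call ended under most alternatives, with a highest adjusted p of 0.262 after length and GC correction. Ddit4 and Sdf2l1, at -0.03 and -0.18, did not pass, and Ddit3 and Dnajb9, at -0.34 and -0.30, passed only under some alternatives, among them length correction (adjusted p = 0.0142 and 0.0378). After length and GC correction Ddit3 was at -0.46 (limma adjusted p = 0.00785), but Dnajb9 was at 0.02 (adjusted p = 0.855). Of 20 interferon response genes 7 passed the filter on low values, and all 7 fell, also when adjusted over the list alone, with a mean log2 change of -0.71 and a camera adjusted p of 0.00267. The adjusted p was 0.335 with an estimated correlation. After quantile normalization 5 of the 7 fell with a call, as did 5 without WT replicate 2. Without the filter 8 of the 20 fell with a call, and the mean was -0.33 (camera adjusted p = 0.000658). Ifit2 fell from 4.51 ± 0.80 to 1.89 ± 0.41 FPKM and Isg15 from 2.95 ± 0.34 to 0.98 ± 0.55 FPKM. Of 14 p53 targets 2 rose and 8 fell, also when adjusted over the list alone, with a mean of -0.55 and a camera adjusted p of 0.0124. With an estimated correlation the adjusted p was 0.335. Ccng1 fell from 114 ± 7.5 to 35.1 ± 8.1 FPKM and the death receptor Fas from 4.47 ± 0.56 to 1.38 ± 0.062 FPKM, as did Plk2, from 318.8 ± 20 to 108.2 ± 4.8 FPKM, in a stretch of chromosome 13 where its neighbours also fell. The cell cycle inhibitor Cdkn1a was higher, from 600.9 ± 65 to 777.9 ± 57 FPKM (limma adjusted p = 0.0355), but its call ended under many alternatives, among them leaving out WT replicate 1 (0.0782), length and GC correction (0.0771) and quantile normalization (0.958), and no p53 target rose under the former 2.

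**Figure D2:**
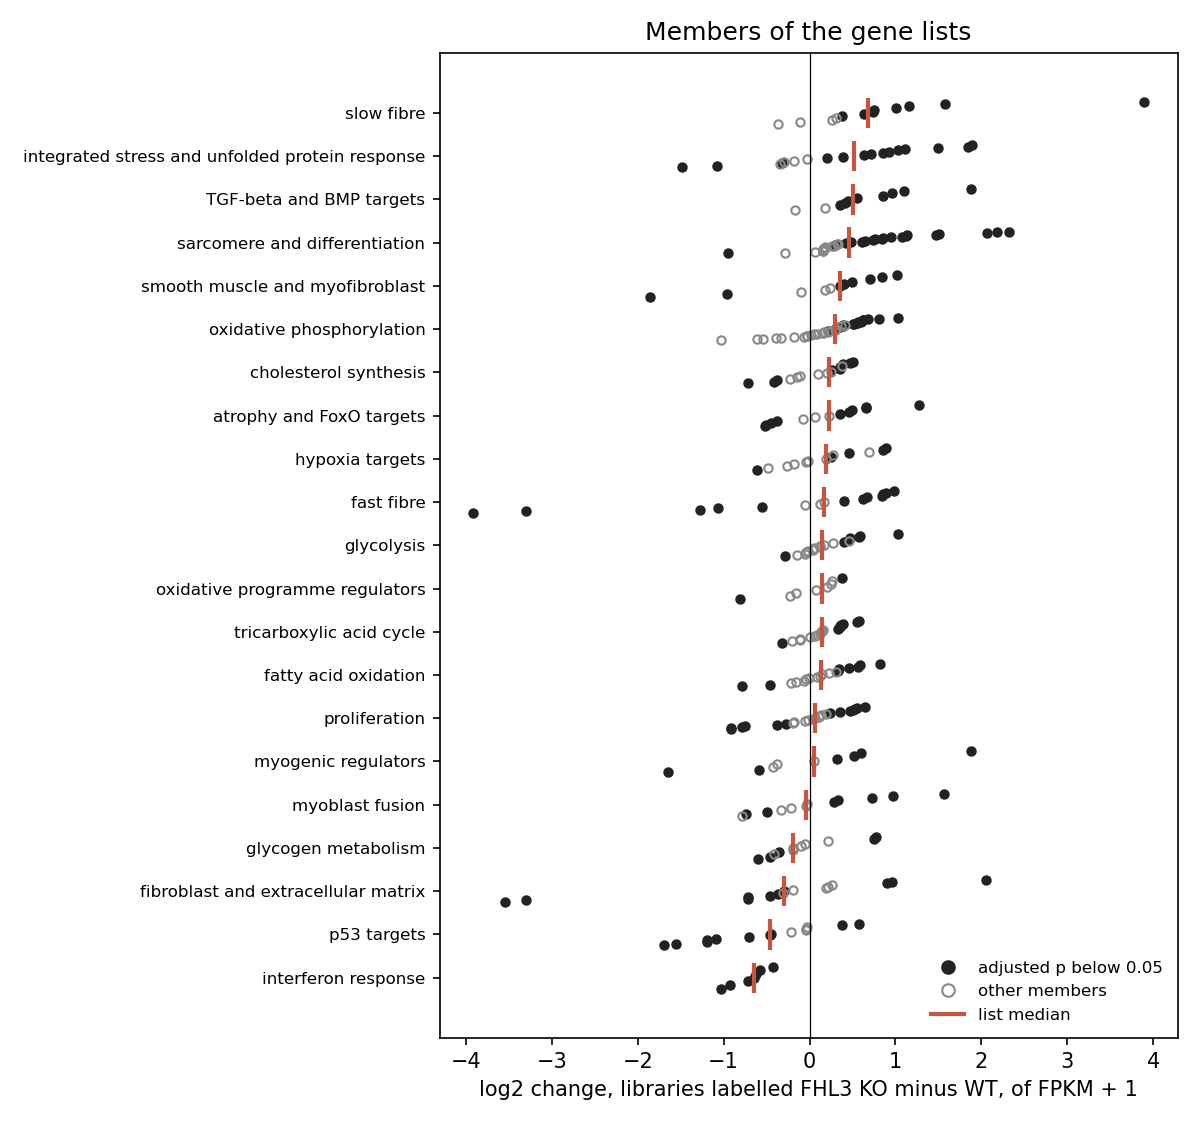
Log2 changes of FPKM + 1 (libraries labelled FHL3 KO minus WT, 3 each) of the measured members of 21 gene lists. Filled points passed an adjusted p of 0.05, open points did not, and red lines mark list medians, which run from -0.65 for interferon response to 0.69 for slow fibre.

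The remaining lists gave no camera call. Of 23 proliferation genes 7 rose and 6 fell (8 and 6 adjusted over the list alone, 4 to 8 and 4 to 7 over the alternatives), with a mean of -0.02, a median of 0.07 and an upward camera adjusted p of 0.655. Ccnb1 rose from 18.5 ± 1.1 to 29.8 ± 3.1 FPKM and Kif11 fell from 7.60 ± 1.7 to 3.56 ± 0.77 FPKM. Of 13 atrophy and FoxO targets 6 rose and 4 fell (7 and 4 adjusted over the list alone, 4 to 8 and 0 to 4 over the alternatives, 5 and 1 without WT replicate 1, camera adjusted p = 0.314), with the ubiquitin ligase Trim63 rising from 13.5 ± 1.2 to 33.9 ± 1.6 FPKM. Hypoxia targets gave 4 rises and 1 fall of 13 (6 and 2 adjusted over the list alone), and cholesterol synthesis genes 6 and 3 of 16 (9 and 4 adjusted over the list alone, 2 to 7 and 1 to 4 over the alternatives), each with a camera adjusted p of 0.331. Of markers of other cell types, 3 adipocyte genes were measured, of which Cebpa rose and Lpl and Pparg fell, and 3 osteoblast genes, of which Spp1 and Dmp1 rose. The Pparg call (limma adjusted p = 0.0323) ended with the replicate block (0.0536), without a filter (0.0938), after quantile normalization (0.0889), without WT replicate 1 (0.0769) or 2 (0.0513) and without the replicate 1 (0.092) or 3 (0.0861) labelled FHL3 KO, with a lowest adjusted p of 0.0148 over the alternatives. The Dmp1 call (0.0137) ended without a filter (0.0576, from 0.00665 over the alternatives). None of the 13 endothelial and leukocyte markers reached the filter of 1 FPKM in a group mean.

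Log2 changes varied with gene properties. Across 11075 protein-coding genes, which are not independent replicates, the log2 change had a Spearman correlation of 0.42 with GC content and of -0.27 with exon length. The length trend was not shared by all libraries. Between WT replicate 3 and the replicate 2 labelled FHL3 KO the correlation with length was 0.02, and in the longest eighth of genes these 2 libraries deviated from the gene means by medians of -0.017 and 0.013, against 0.30 and 0.11 in WT replicates 1 and 2 and -0.20 and -0.21 in the replicates 1 and 3 labelled FHL3 KO. The median change ran from -0.50 for genes with up to 43.1% GC to 0.19 for genes above 57.3% GC. The size of the GC trend also varied between libraries. In genes with up to 43.1% GC the median deviations were 0.41, 0.23 and 0.10 in WT replicates 1 to 3. They were -0.28, -0.07 and -0.40 in the replicates 1 to 3 labelled FHL3 KO. Chromosome 8 genes lay above the other autosomes by a median of 0.41, and 336 of 615 rose, including Egln1, Map1lc3b, Fbxo31 and Msmo1.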

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

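The scaling, length, GC, filter at 5 FPKM, zero and chromosome 8 alternatives were chosen after the data were seen; the others were planned. No log2 change of a named gene and no list mean reversed its sign with a call on either side, but the direction of the fast fibre list was up with camera (adjusted p = 0.826) and down with fry, with a call (adjusted p = 0.0244). Fhl3 stayed higher in the libraries labelled FHL3 KO, and called, under every alternative run (log2 change 0.64 to 0.94). Of 1834 recalculations of named genes 1802 stayed called or stayed uncalled, 25 lost the call and 7 gained it. For gene lists the numbers were 371, 13 and 14 of 398. Uncalled results counted as kept whatever their sign, and some list means near 0 changed it. The mean of glycogen metabolism, for example, went from -0.057 to 0.028 after length and GC correction. A threshold of 0.01 left 2695 genes changed, 1337 higher and 1358 lower. Leaving out a library gave 3272 to 5273 genes changed, 1605 to 2422 higher and 1667 to 2851 lower; the lowest of each came without WT replicate 2, and without the replicate 1 labelled FHL3 KO 1749 were lower. The number changed at least 2-fold was 1419 with a pseudocount of 0.1 and 1337 with scaling to the same sum. A smaller pseudocount shrinks low genes less by construction, whereas the scaling also moved the median of all genes to -0.12 and raised the genes tested to 14046, and the cause of its rise was not tested. Values of lists below are mean log2 changes. Without a filter, glycolysis (0.23, adjusted p = 0.0185) and the tricarboxylic acid cycle (0.16, adjusted p = 0.00368) gained a call, the latter also without chromosome 8 (0.16, adjusted p = 0.0477); leaving out single libraries gave 0.15 to 0.30 for glycolysis and 0.14 to 0.18 for the cycle, with calls for both without WT replicate 3 and for glycolysis also without the replicate 2 labelled FHL3 KO. The means fell to 0.084 and 0.028 after quantile normalization (adjusted p = 0.774 and 0.818) and to 0.13 and 0.054 with scaling to the same sum (adjusted p = 0.0566 and 0.138), and that of glycolysis to 0.13 after length and GC correction (adjusted p = 0.403). After quantile normalization oxidative phosphorylation (0.081, adjusted p = 0.0981) and the stress response (0.35, adjusted p = 0.0702) lost their calls, the latter also after length correction (0.37), length and GC correction (0.36) and the filter at 5 FPKM (0.41). With an estimated correlation all 7 called lists lost their calls: slow fibre (0.85), sarcomere (0.65), oxidative phosphorylation (0.23), TGF-beta and BMP targets (0.66), interferon response (-0.71), stress response (0.41) and p53 targets (-0.55). With fry oxidative phosphorylation lost its call (0.23, adjusted p = 0.0691), and fast fibre (-0.31), fusion (0.10), the cycle (0.16), fatty acid oxidation (0.13), matrix (-0.35), smooth muscle (0.12), atrophy (0.17) and hypoxia (0.15) gained one, in a test that compares no list with other genes. The cause of these changes was not tested. Weighted by exon length, the myosin share differences were -1.50 (Myh2), 32.8 (Myh3), -15.4 (Myh4), 13.4 (Myh7) and -1.23 percentage points (Myh8), each with its sign kept. Length correction gave 5587 calls, of which 4613 were shared, and length and GC correction 5278, of which 3867 were shared. With the replicate number as a block 4759 genes were called, 4544 of them shared. Deviations of same-numbered libraries correlated at -0.13, -0.06 and 0.32, and not every library correlated best with its own number. These values show no pairing by number but, with 3 libraries per group, cannot exclude it. The alternatives that need counts were not run because the table holds FPKM. Each of the 5 counts below was reached by 1 of the 10 splits of the 6 libraries, the real one, and 10 splits are too few for a share under 0.05. The real split and the highest other gave 5112 and 1 genes changed, 2462 and 1 higher, 2650 and 1 lower, 761 and 1 changed at least 2-fold, and 7 and 4 gene lists called. Each of the other splits called 1 to 4 lists while calling no more than 1 gene, so list calls arose without the labelled grouping. Without counts, the precision of low values cannot be given.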

Other observations

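The tests in this part were chosen after the results were seen, except the liver and lung marker tests and the length and GC test of chromosome 8, whose outcomes were set out before they were run. Directions again refer to the libraries labelled FHL3 KO, whose Fhl3 RNA was higher than in WT.

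Of 121 gene families of at least 10 tested members, taken from symbol stems or from the mitochondrial genome, 6 were called by camera. Among genes of the mitochondrial ribosome 13 of 29 Mrps genes rose and none fell, and 18 of 49 Mrpl genes rose and 1 fell (mean log2 changes of 0.31 and 0.25, adjusted p = 0.00119 and 0.00248, or 0.995 for both with an estimated correlation). Of 13 protein-coding genes of the mitochondrial genome 11 fell and 0 rose, at a mean of -0.88 (adjusted p = 0.00124, or 0.995 with an estimated correlation), with mt-Atp8 and mt-Nd4l at -1.63 and -1.47. Cytosolic Rpl genes rose in 19 of 49 cases, while zinc finger (Zfp) genes fell in 122 of 269 and rose in 20, and centrosomal Cep genes fell in 15 of 34 and rose in 2 (adjusted p = 0.00907, 0.0011 and 0.00798, or 0.995 for each with an estimated correlation). After length and GC correction the Mrps and Mrpl calls stayed (adjusted p = 0.00883 and 0.0488), and the other 4 had an adjusted p of 0.103 with smaller means, -0.43 for the mitochondrial genome, 0.17 for Rpl, -0.12 for Zfp and -0.165 for Cep. Quantile normalization ended the Mrpl, Zfp, Cep and Rpl calls, with means of 0.20, -0.16 and -0.25 for the former 3 and 0.047 for Rpl (0.25, -0.29, -0.37 and 0.25 before). With scaling to the same sum, which moved the median of all genes to -0.12, all 6 calls stayed. There 9 Mrpl genes rose and 2 fell (mean 0.15), the Rpl mean was 0.14, and 8 Zfp genes rose and 123 fell.

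On chromosome 13 (GRCm38) 5 neighbouring tested genes between 110395046 and 112384002 fell together: Plk2, Gpbp1, Mier3, Map3k1 and Ankrd55, at log2 changes of -1.55, -2.04, -1.94, -1.04 and -2.04. Their flanking tested genes Pde4d and Il6st were at -0.09 and 0.21. In 1000 shuffled gene orders the share with 5 neighbours of a median as low (-1.94) anywhere was 0.005. This argues against a chance order for runs of 5 genes. The length of 5 was set after the run was seen, so the share does not allow for other lengths. Gapdh ranged from 32.7 to 87.2 FPKM in WT and from 31.0 to 68.9 FPKM in the libraries labelled FHL3 KO, with its pseudogene Gapdh-ps15 at 56.2 to 78.2 FPKM over the 6 libraries, so Gapdh is uncertain here.

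Fhl3 RNA was 1.85-fold higher in the libraries labelled FHL3 KO. A single mislabelled library is argued against by the lowest of these libraries lying at 1.59 times the highest WT library, and scaling, length or GC content by a log2 change of at least 0.64 under every setting run. Extra copies of the region are argued against by the 17 tested protein-coding genes within 1 Mb, whose median log2 change was 0.14 (SE 0.098). An exchange of the labels of the whole groups cannot be told apart from a knockout allele that leaves or raises the transcript, since the table holds 0 genotype markers other than Fhl3. The biological explanation, a response of the locus to loss of the protein, stays open and was not tested.

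Chromosome 8 genes were higher in the libraries labelled FHL3 KO, by a median of 0.41 log2 units over the other autosomes (a ratio of 1.33). Length and GC content are argued against as the whole cause by a difference of 0.35 after correction, chance placement by 0.0001, the smallest share 10000 relabellings can give, and a few regions by 100% of 12 bins of 10 Mb lying above the other autosomes by over 0.1. Chromosome 8 was not alone, since chromosomes 3, 10, 16 and X, at -0.20, -0.18, -0.16 and -0.15, also reached 0.0001 before correction, and chromosomes 10 and 13, at -0.19 and 0.155, after it. More copies of chromosome 8 in the line labelled FHL3 KO may explain the shift, as 81.5% of its genes lay above the median of the other autosomes, and this remains a hypothesis without DNA data. A response to FHL3 loss spread over the chromosome was not tested and stays open.

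WT replicate 1 held transcripts of other tissues: Alb at 56.0, Trf at 23.1, Scgb1a1 at 17.2, Hp at 13.4 and Sftpc at 3.34 FPKM, each at 0.30 FPKM or lower in the other libraries. Of 26 liver markers not looked at before, 61.5% were at least 10 times higher in this library than in every other, while 1 of the 26 reached 1 FPKM in another library, so liver RNA or reads in this library are a candidate source. The share was 33.3% of 12 lung markers, which leaves lung open, 4 of 10 blood markers (1 of which another list holds), 1 of 10 heart and of pancreas markers and 0 of 10 kidney and of brain markers, of which 2, 5, 3, 0 and 1 reached 1 FPKM in another library. Unlike the 63 genes peculiar to this library, these markers were counted without a floor of 1 FPKM. The lung markers counted were all below it, at 0.62, 0.15, 0.61 and 0.11 FPKM in WT replicate 1. Those of blood included Hbb-bs at 1.777 and Ptprc at 0.0093 FPKM, and those of liver Hpd at 1.387 and G6pc at 0.067 FPKM. RNA of other tissues is argued against as the source of the higher Myh4 in WT, since WT replicates 2 and 3 averaged 20.1 times the Myh4 of the libraries labelled FHL3 KO. The 63 genes peculiar to this library made up 0.077% of its FPKM sum, and no biological explanation was tested.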
